A study of Mus musculus with 8 samples.

How the data were processed

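RNA was measured in the mouse dendritic cell line DC2.4, kept in low-serum medium for 4 h and then left untreated or given 250 PNU/ml of an extract of house dust mite (HDM), timothy grass (Grass) or cat hair (Cat) for 4 h, per the labels. Each of the 4 groups holds 2 libraries, which the series' design text calls independent. The labels name no vehicle given to the untreated cells. Libraries were made from mRNA-enriched RNA with a stranded kit, per the labels' protocols. The submitters' processing notes list Bowtie2 2.1.0, RSEM 1.2.15, edgeR without a version and the mouse build mm9, with no role or order for any of them. The annotation and the strand setting of the counting are not stated.

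The deposited table of all genes is named as raw counts, but its values are a depth-scaled signal. Every nonzero value in a library was a whole number of reads times 1 step per library, with a largest distance from a whole read of 9.9e-10, and the columns summed to between 975215 and 1047501. The deposited signal thus corresponds to RPM of a scaled library size. The authors' 3 tables of changed genes repeat these values and add a deposited fold (signed and linear, allergen over untreated), a deposited p-value and a deposited FDR. Dividing by the step gave 31.94 to 43.32 M reads per library. Values are given below in the deposited unit, as the mean of a group with its SD.

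Of 24054 rows, 16242 had a read in any library. Rows were tested if their value was at least 0.5 in at least 2 of the 8 libraries, which left 11455. The 27 rows whose symbol had been turned into a date stayed in the tests and are not named. The main test was limma 3.58.1 (R 4.3.3) on log2 of the value plus 0.1, with a trend and robust settings, all 8 libraries in one fit with 4 residual degrees of freedom, and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05 with no fold minimum. The design written before the data were examined assumed counts and named edgeR's quasi-likelihood test with TMM factors and edgeR's own filter (filterByExpr). Since the deposited values are scaled, limma was used instead. The edgeR test could still be run on recovered reads, of which 100% were whole. It was run as an alternative, with the deposited scaling and with TMM and filterByExpr. With TMM and filterByExpr 48.1% of the HDM calls were higher, against 29.6% in the main test. Log2 fold changes therefore refer to the value plus 0.1, which shrinks those of genes with very low values. All adjusted p-values of genes are limma's with Benjamini-Hochberg adjustment unless another tool is named.

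Gene lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested with camera (limma) with a preset correlation between genes of 0.01, adjusted over the lists with at least 5 tested members within a comparison, and again with an estimated correlation. Members called were counted with the adjustment over all genes and adjusted over the list alone. A list's score per library is the mean of its members' log2 values, centred on the 8 libraries. The score of the 6 allergen libraries was set against that of the 2 untreated ones with an exact two-sided permutation test over all 28 splits, a test added after the data were seen. For each comparison with untreated, the named genes were the 10 called genes with the largest change in each direction among those with a mean value of at least 1 and both treated libraries on the same side of both untreated ones, up to 4 members of each list with the smallest p, and a fixed set that included Isg15, Irf7, Cxcl10, Tnf, Il6 and Gapdh. Between extracts the rule took the 5 largest in each direction. Genes outside this rule were chosen after their values were seen. In the comparisons these are Ccne2, E2f1, Ccnd1, Aurkb, Birc5, Ttk, Slfn5, Amd1, Ugt1a6a and the values of Cxcl10 between extracts. In the closing section they are all genes named only there except Il6, Il1b and Ccl17, which were in the fixed set, and Hsp90ab1, which came under the rule.

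The 3 comparisons with untreated share their controls. Overlaps and correlations across genes are therefore given beside 50 simulations of unchanged groups that share simulated untreated libraries. All 8 simulated libraries were drawn from the mean of the real ones. Overlaps are also given beside those of independent lists. The 2 untreated libraries could not be split between comparisons with 2 libraries in each part.

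The fit was tested on simulated data for the comparison of HDM with untreated over 11455 genes. It called 84% of genes changed 1.25-fold, 92% of those changed 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 15 of 11255 unchanged genes. The changed list was recovered and 0 of the unchanged lists were called. Each gene was drawn independently, so the simulation could not show how often lists with correlated members are called falsely. In the data the estimated correlation was 0.65 between members of the interferon list.

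The alternatives were DESeq2's, upper-quartile and TMM scaling factors, no filter, a stricter filter, other pseudocounts, a fit of only the 4 libraries compared, a replicate block, a minimum of 1.5-fold, edgeR 4.0.16, limma-voom and DESeq2 1.42.0 on recovered reads, edgeR's exact test at an unadjusted p under 0.05 and 1.5-fold, removal of a GC and length trend, and leaving out each library. With a library left out, the lone library of its group is assumed to vary like the other groups. GC content and length came from the longest transcript of each gene in a GENCODE annotation of a newer build than mm9, matched by symbol for 99.1% of the tested genes, and no coordinates were used. Genes that share reads with near-identical copies are given as uncertain.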

Results

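DC2.4 is a mouse dendritic cell line, a model of the antigen-presenting cells that take up allergens. Its transcriptome was measured in 8 libraries: 2 untreated, 2 exposed to house dust mite extract (HDM), 2 to timothy grass extract (Grass) and 2 to cat hair extract (Cat), each at 250 PNU/ml for 4 h. Depth was 35.81 and 35.9 M reads in the untreated libraries, 41.8 and 31.94 M with HDM, 43.32 and 37.02 M with Grass, and 35.28 and 36.22 M with Cat. The 10 most abundant genes took 4.71% to 4.94% of the reads in each library. The p-values measure only the spread between these libraries.

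The series title names an antiviral signature, so the first question was how interferon-stimulated antiviral genes responded. In this table their transcripts were lower with each extract than in untreated cells. Of 55 tested members, 37 fell with HDM, 39 with Grass and 32 with Cat, and 46, 46 and 47 fell when adjusted over the list alone. With all 8 libraries, limma called 0 members higher in the 3 comparisons (0 at an unadjusted p under 0.05). EdgeR and DESeq2 on recovered reads also called 0 higher. The authors' own tables, which hold no fold below 1.501, list 0 as higher. Dhx58, a cytosolic RNA sensor of the RIG-I family, fell from 30.4 ± 3.8 (SD, n = 2) in untreated cells to 19.3 ± 0.89 with HDM, 20.8 ± 0.24 with Grass and 21.5 ± 1.5 with Cat. Its log2 fold changes were -0.65, -0.54 and -0.50, each with an SE of 0.07. Tor3a, an interferon-induced ATPase, changed by -0.36, -0.42 and -0.33 (SE 0.05 each), and Oas2, an enzyme of the RNase L pathway, by -0.29, -0.29 and -0.33 (SE 0.04 each). Ifih1, which encodes the RNA sensor MDA5, changed by -0.57 with HDM and -0.55 with Grass (SE 0.07 each). The ubiquitin-like Isg15 was at 44.7 ± 9.1 (SD, n = 2) in untreated cells and at 27.2 ± 4.2, 26.3 ± 0.68 and 27.3 ± 0.082 with HDM, Grass and Cat, with limma adjusted p-values of 0.049, 0.037 and 0.076. The calls of Isg15 are near the threshold: the HDM call ended with the 3 other scalings, with edgeR, without HDM 2 and without any 1 Grass or Cat library, and the Grass call without any 1 Grass or Cat library. The interferon regulatory factor Irf7 was called only with HDM (-0.67, SE 0.15, limma adjusted p = 0.036), a call that ended without any 1 of the 6 allergen libraries. Ifnb1, which encodes interferon beta, had 2 to 7 reads per library and was below the filter. A fall or a small change in it was not detectable at this depth. A rise to the filter's value of 0.5 would have been seen, and its highest value in any library was 0.204.

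The median log2 fold change of the list was -0.42 with HDM, -0.44 with Grass and -0.41 with Cat. Camera gave adjusted p = 1.6e-15, 5.8e-14 and 1.1e-25 with the preset correlation, and adjusted p = 0.42, 0.59 and 0.44 with an estimated correlation, which was 0.65 between members. All 6 allergen libraries lay below both untreated ones in 48 of 55 members, where chance gives 2, but these members are not independent of each other. The list score was lower by 0.44 in the allergen libraries (exact two-sided permutation p = 0.036, the smallest that 28 splits allow, Benjamini-Hochberg adjusted 0.09 over 20 lists). Other lists reached the same p, such as glycolysis and hypoxia (-0.14), Nrf2 (0.19) and heat shock genes (0.07). The permutation test thus does not single out interferon-stimulated genes. In the interferon-stimulated score the 2 untreated libraries differed from each other by 0.26. Without untreated 2, the higher of these, 34, 38 and 34 members fell and Slfn5 rose with HDM (0.26, SE 0.08, limma adjusted p = 0.024). The number lower with HDM was 22 without HDM 2, and that with Cat was 52 without untreated 1, 18 without Cat 1 and 14 without Cat 2.

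**Figure D1:**
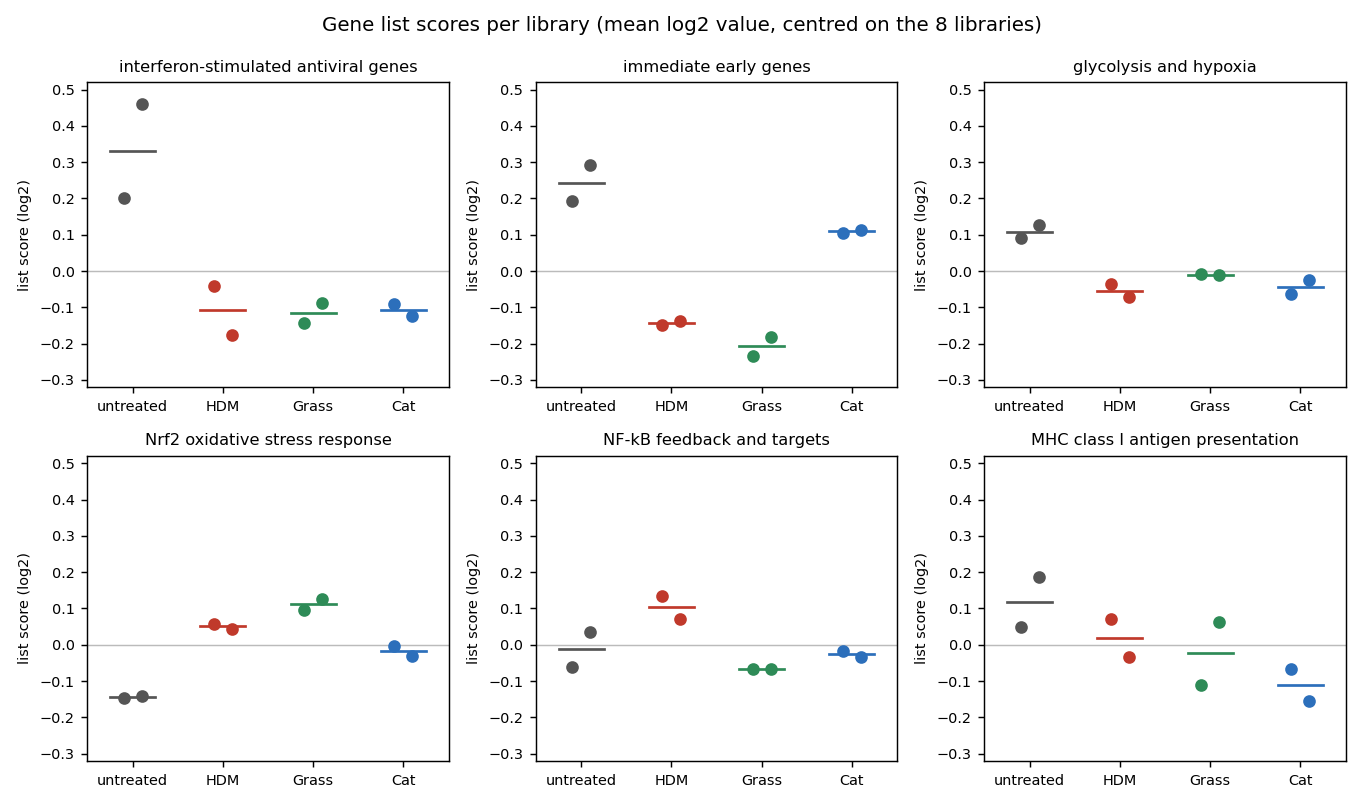
Scores of 6 gene lists (mean log2 value of the tested members, centred on the 8 libraries; y axis, log2 units) for untreated, HDM, Grass and Cat cells, with 1 point per library and a line at each group's mean. The interferon-stimulated score is 0.201 and 0.459 in the untreated libraries and between -0.175 and -0.041 in the 6 allergen libraries.

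HDM against untreated cells addressed the response to the mite extract. The largest rise among the named genes was in Ahrr, the repressor of the aryl hydrocarbon receptor, which went from 1.62 ± 0.027 to 12.1 ± 0.08 (SD, n = 2 each; log2 fold change 2.82, SE 0.14). Cxcl2, a neutrophil chemokine, rose from 3.06 ± 0.91 to 9.06 ± 0.97 (1.56, SE 0.15), and Mmp8, a neutrophil collagenase, from 0.943 ± 0.15 to 3.87 ± 0.27 (1.93, SE 0.20). Csf2rb, the shared beta subunit of the receptors for GM-CSF, IL-3 and IL-5, rose from 53.9 ± 1.2 to 141 ± 1.4 (1.38, SE 0.04). The size of this change is uncertain, as is that of the near-identical copy Csf2rb2, because reads may be split between the pair. The authors' deposited folds with HDM were 2.69 for Csf2rb and 2.23 for Csf2rb2. Il4ra, the IL-4 receptor alpha chain, rose from 8.95 ± 0.098 to 15.2 ± 0.19 (0.76, SE 0.08).

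NF-kB feedback genes and targets rose with HDM in 10 of 23 and fell in 2 (11 and 2 adjusted over the list alone), among them Tnfaip2 (0.33, SE 0.03), Birc3 (0.41, SE 0.06) and Tnip1 (0.32, SE 0.04). Of 20 oxidative stress genes under Nrf2 control, 11 rose and 1 fell (11 and 1 adjusted over the list alone), including the cystine transporter Slc7a11 (0.76, SE 0.04), Osgin1 (0.84, SE 0.07) and Srxn1 (0.32, SE 0.03). Immediate early genes went the other way: 19 of 29 fell and 1 rose (20 and 1 adjusted over the list alone), with Egr1 at 21.1 ± 0.06 against 53.1 ± 2.8 (-1.33, SE 0.05), Egr3 at -1.44 (SE 0.14) and Fosb at -1.36 (SE 0.13). Glycolysis and hypoxia genes fell in 19 of 25 and rose in 1 (22 and 1 adjusted over the list alone), including the glucose transporter Slc2a1 (-0.40, SE 0.03) and hexokinase Hk2 (-0.31, SE 0.03), but only 8 fell under upper-quartile scaling. Inflammatory cytokines were mixed, with 4 of 14 higher and 5 lower (5 and 5 adjusted over the list alone): Csf1 rose by 0.35 (SE 0.03), while Tnf fell by 0.49 (SE 0.06) and Ccl3 by 0.93 (SE 0.07). Cell cycle genes went both ways, with 8 higher and 17 lower of 33 (9 and 17 adjusted over the list alone), and 13 higher under upper-quartile scaling. The mitotic members Plk1 (-0.61, SE 0.04), Ccnb1 (-0.52, SE 0.03) and Cdc20 (-0.49, SE 0.03) fell, while Aurkb, Birc5 and Ttk were not called. Ccne2 (0.34, SE 0.03) and E2f1 (0.25, SE 0.04), chosen after their values were seen, rose. Ccnd1, which encodes cyclin D1 and was chosen in the same way, fell (-0.36, SE 0.04). Of 22 p53 targets and apoptosis genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone), including Bbc3 (0.31, SE 0.04) and Sesn1 (0.29, SE 0.05). MHC class I genes fell in 10 of 19 and rose in 1 (11 and 1 adjusted over the list alone), for example Tap1 (-0.30, SE 0.05), but in 5 without HDM 2 and in 5 under upper-quartile scaling.

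In all, limma called 1056 genes higher and 2513 lower with HDM of 11455, of which 105 and 113 changed at least 1.5-fold. The median size of called changes was 0.19 on the log2 scale. Of the calls, 29.6% were higher under the deposited scaling, 46.9% with DESeq2's factors (1486 higher, 1684 lower), 47% with TMM and 65.2% with upper-quartile factors (2169 higher, 1156 lower), so the balance of small changes depends on the scaling. Without HDM 1 the number higher was 613, and without HDM 2 the number lower was 1660. Camera with the preset correlation gave adjusted p = 0.00021 for the NF-kB list, 1.3e-07 for Nrf2, 4e-07 for immediate early genes, 2.3e-06 for glycolysis and hypoxia, 0.0042 for p53 targets, 0.036 for MHC class I, 0.068 for cell cycle and 0.99 for cytokine genes. With an estimated correlation, adjusted p = 0.42 for NF-kB, 0.32 for Nrf2, 0.42 for immediate early, glycolysis and p53 genes, and 0.74 for MHC class I, and no list passed in any of the 6 comparisons.

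Grass against untreated cells addressed the response to the pollen extract. Hmox1, the heme-degrading enzyme of the oxidative stress response, rose from 480 ± 38 to 828 ± 32 (SD, n = 2 each; log2 fold change 0.79, SE 0.05), and Slc7a11 rose from 48.6 ± 0.15 to 82.9 ± 0.78 (0.77, SE 0.04). Trp53inp1, a p53-induced stress protein, rose from 2.66 ± 0.62 to 6.24 ± 0.18 (1.22, SE 0.15), and Il4ra rose to 15 ± 0.034 (0.74, SE 0.08). The growth-response factor Egr1 fell from 53.1 ± 2.8 to 18 ± 0.82 (-1.56, SE 0.05). The chemokines Ccl3 and Ccl4 fell, Ccl3 from 216 ± 24 to 103 ± 2.6 (-1.06, SE 0.07) and Ccl4 from 78.2 ± 12 to 34.2 ± 2.9 (-1.18, SE 0.12), as did Tnf (-0.82, SE 0.06). H1f0, a linker histone, fell from 283 ± 5.3 to 122 ± 1.9 (-1.21, SE 0.03).

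Nrf2 genes rose with Grass in 13 of 20 and fell in 1 (14 and 1 adjusted over the list alone), including Osgin1 (0.83, SE 0.07), Srxn1 (0.49, SE 0.03) and Gclm (0.44, SE 0.03). Immediate early genes fell in 20 of 29 and rose in 2 (20 and 3 adjusted over the list alone), including Egr3 (-1.72, SE 0.14), Phlda1 (-0.92, SE 0.06) and Zfp36 (-0.91, SE 0.04), and 0 rose without untreated 1 or without Grass 1, and 1 without Grass 2. Glycolysis and hypoxia genes fell in 16 of 25 and rose in 1 (18 and 1 adjusted over the list alone), including Slc2a1 (-0.43, SE 0.03), but in 10 with DESeq2's or TMM factors and in 6 with upper-quartile factors. Cytokines rose in 4 of 14 and fell in 6 (4 and 6 adjusted over the list alone), with Csf1 higher (0.43, SE 0.03), and 2 rose without untreated 1 or without Grass 2. NF-kB genes rose in 3 of 23 and fell in 6 (3 and 7 adjusted over the list alone), but rose in 5 without untreated 2, 7 with DESeq2's factors and 8 with upper-quartile factors. Cell cycle genes rose in 8 of 33 and fell in 17 (13 and 18 adjusted over the list alone), with Plk1 lower (-0.67, SE 0.04) and Ccne2, chosen after its values were seen, higher (0.52, SE 0.03), and 13 rose without untreated 1 and with DESeq2's factors. The p53 targets rose in 7 of 22 and fell in 1 (10 and 3 adjusted over the list alone), and rose in 11 with DESeq2's factors. MHC class I genes fell in 9 of 19 and 10 did not pass (9 lower adjusted over the list alone), including Nlrc5 (-0.20, SE 0.04), and fell in 5 under upper-quartile scaling.

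Limma called 1193 genes higher and 2909 lower with Grass, of which 117 and 111 changed at least 1.5-fold. The share higher was 29.1% under the deposited scaling, 46.1% with DESeq2's factors (1669 higher, 1953 lower), 46.6% with TMM and 64.8% with upper-quartile factors (2459 higher, 1338 lower). Without Grass 1 the number higher was 775, and without Grass 2 it was 787. Camera with the preset correlation gave adjusted p = 4.7e-11 for Nrf2, 2.5e-07 for immediate early genes, 0.00056 for glycolysis and hypoxia and 0.0031 for p53 targets, and 0.69, 0.23, 0.23 and 0.065 for NF-kB, cytokine, cell cycle and MHC class I genes. With an estimated correlation, adjusted p = 0.16 for Nrf2 and 0.59 for the other 3 that passed.

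Cat against untreated cells addressed the response to the cat hair extract, which changed fewer genes. Slc7a11 rose from 48.6 ± 0.15 to 76.3 ± 1.7 (SD, n = 2 each; log2 fold change 0.65, SE 0.04), and Slc22a23, a transporter-family member, from 15.7 ± 0.66 to 23.8 ± 1.7 (0.60, SE 0.07). H1f0 fell from 283 ± 5.3 to 153 ± 2.3 (-0.89, SE 0.03), and Adm, the hypoxia-responsive hormone adrenomedullin, from 15.4 ± 0.56 to 9.05 ± 0.71 (-0.76, SE 0.09). Egr1 fell from 53.1 ± 2.8 to 38 ± 0.037 (-0.48, SE 0.05). Tnf (limma adjusted p = 0.15), Il4ra (0.095) and Cd86, a co-stimulatory ligand (0.97), were not called with Cat, and Cd86 was not called with HDM (0.47) or Grass (0.87).

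Nrf2 genes rose with Cat in 10 of 20 and fell in 1 (11 and 1 adjusted over the list alone), including Srxn1 (0.36, SE 0.03), Gclm (0.26, SE 0.03) and Gclc (0.25, SE 0.04). Glycolysis and hypoxia genes fell in 18 of 25 and 7 did not pass (23 lower adjusted over the list alone), including Bnip3 (-0.41, SE 0.03) and Ndrg1 (-0.31, SE 0.03), but in 11 under upper-quartile scaling. The control gene Gapdh, itself glycolytic, changed by -0.13, -0.08 and -0.09 (SE 0.02 each) with HDM, Grass and Cat. Its Grass call ended with DESeq2's, TMM and upper-quartile factors and without Grass 2, and its Cat call with upper-quartile factors and without Cat 1. Immediate early genes fell in 12 of 29 and 17 did not pass (13 lower adjusted over the list alone), including Zfp36 (-0.25, SE 0.04), and in 7 without Cat 2. MHC class I genes fell in 10 of 19 and 9 did not pass (11 lower adjusted over the list alone), including Tap1 (-0.26, SE 0.05), and in 6 without untreated 2 or without Cat 2. Cell cycle genes rose in 9 of 33 and fell in 17 (11 and 17 adjusted over the list alone), with Plk1 (-0.44, SE 0.04) and Cenpe (-0.40, SE 0.03) lower. Few members changed in the NF-kB (2 of 23 higher, 1 lower), cytokine (3 of 14 lower) and p53 lists (3 of 22 higher, 2 lower), with the same counts adjusted over the list alone. The NF-kB count higher ranged from 0 to 6 with 1 library left out (0 without untreated 1, Cat 1 or Cat 2, 1 without any 1 HDM or Grass library, 6 without untreated 2) and was 5 with DESeq2's or TMM factors. The cytokine count lower was 6 without untreated 1 and 1 without Cat 2 or any 1 Grass library, and the p53 count higher was 6 without untreated 2.

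Limma called 497 genes higher and 1563 lower with Cat, of which 19 and 26 changed at least 1.5-fold. The share higher was 24.1% under the deposited scaling, 41% with DESeq2's factors (762 higher, 1095 lower), 41.1% with TMM and 55.7% with upper-quartile factors (1048 higher, 834 lower). Without Cat 1 the counts were 244 higher and 945 lower, and without Cat 2 they were 201 and 754. Camera with the preset correlation gave adjusted p = 1.2e-07 for Nrf2, 7e-11 for glycolysis and hypoxia, 1e-05 for MHC class I and 0.0011 for immediate early genes, and adjusted p = 0.33, 0.35, 0.44 and 0.44 with an estimated correlation. The preset p was 0.2, 0.19, 0.19 and 0.14 for the NF-kB, cytokine, cell cycle and p53 lists.

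**Figure D2:**
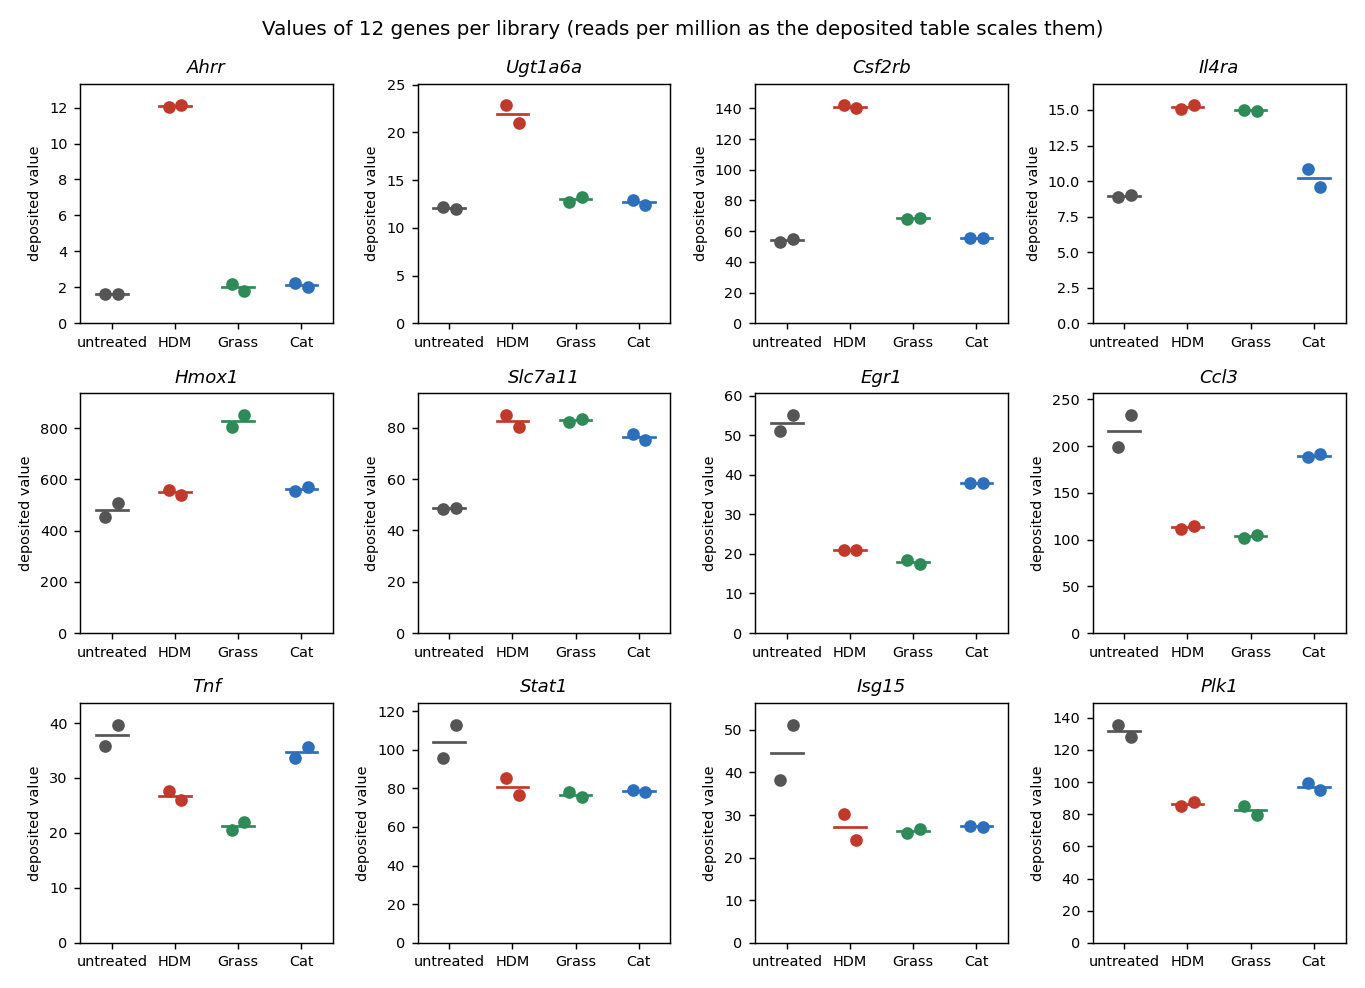
Deposited values (y axis, reads as the deposited table scales them) of 12 genes in each library, with 1 point per library and a line at each group's mean (n = 2). Ahrr is at 12 and 12.1 in the HDM libraries and at no more than 2.21 in the 6 others, and Ugt1a6a, which shares exons with Ugt1a6b and is uncertain, was chosen for this figure after its values were seen.

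The extracts were then compared with each other, to ask which parts of the response differ between allergens. HDM stood apart from the others in Ahrr, which was higher than with Grass by 2.55 and than with Cat by 2.46 on the log2 scale (SE 0.14 each). Csf2rb, uncertain in size because of its copy, was higher than with Grass by 1.04 and than with Cat by 1.34 (SE 0.04 each). Mmp8 was higher by 1.39 and 1.22 (SE 0.20 each). Grass exceeded HDM in Hmox1, at 828 ± 32 against 549 ± 12 (SD, n = 2 each; -0.59 for HDM against Grass, SE 0.05). Grass was lower than Cat in Egr1 (-1.07, SE 0.05), Egr2 (-1.48, SE 0.16) and Sema6d, which encodes a semaphorin (-1.08, SE 0.06), and higher in S1pr1, a sphingosine-1-phosphate receptor (0.82, SE 0.11). The calls of Egr2 and Trp53inp1 (0.93, SE 0.15) between Grass and Cat ended with DESeq2. Between extracts, Cxcl10 was the only interferon-stimulated member called: 0.37 for HDM against Grass (SE 0.08) and -0.26 for Grass against Cat (SE 0.08). Adjusted over the list alone, the call for Grass against Cat did not pass. With 1 library left out, 0 to 2 members were called higher and 0 to 2 lower for HDM against Grass, 0 to 1 and 0 to 3 for HDM against Cat, and 0 to 1 and 0 to 3 for Grass against Cat.

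NF-kB genes were higher with HDM than with Grass in 5 of 23 (9 adjusted over the list alone), and higher than with Cat in 6 and lower in 1 (9 and 1 adjusted over the list alone). Cytokines were higher with HDM than with Grass in 3 of 14 (6 adjusted over the list alone), a count that was 1 without HDM 1 or Grass 1 and 8 without either untreated library. Nrf2 genes were lower with HDM than with Grass in 6 of 20 (8 adjusted over the list alone), and in 2 without any 1 of those 4 libraries. They were higher with Grass than with Cat in 9 (12 adjusted over the list alone), and in 14 without either untreated library, 4 without Grass 1 or Cat 1, 3 without Cat 2 and 2 without Grass 2. Immediate early genes were lower with HDM than with Cat in 15 of 29 and higher in 2 (16 and 3 adjusted over the list alone), with 9 lower without Cat 1 and 1 higher without HDM 2 or Cat 2. They were lower with Grass than with Cat in 15 and higher in 2 (17 and 3 adjusted over the list alone), with 1 higher without Grass 1 or Cat 2. Camera with the preset correlation gave adjusted p = 5.7e-10 and 6.1e-05 for NF-kB, 9.6e-07 for cytokines, 1.1e-06 and 5.8e-09 for Nrf2, and 3.1e-07 and 9.7e-08 for immediate early genes, in the order given. With an estimated correlation, adjusted p = 0.36 and 0.63, 0.36, 0.36 and 0.22, and 0.6 and 0.53, respectively.

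Limma called 194 genes higher and 71 lower for HDM against Grass, 337 and 552 for HDM against Cat, and 410 and 943 for Grass against Cat. The shares higher were 73.2%, 37.9% and 30.3% under the deposited scaling, 69%, 46.7% and 43.1% with DESeq2's factors and 65.7%, 60.2% and 58.1% with upper-quartile factors. The HDM and Grass total of 265 was 108, 112, 122 and 117 without HDM 1, HDM 2, Grass 1 and Grass 2, and 556 and 566 without untreated 1 and 2. The HDM and Cat total of 889 was 438, 484, 451 and 474 without HDM 1, HDM 2, Cat 1 and Cat 2, and the Grass and Cat total of 1353 was 771, 535, 634 and 693 without Grass 1, Grass 2, Cat 1 and Cat 2.

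Much of the response was called in common. Across the 11455 genes, which are not independent replicates, log2 fold changes correlated at r = 0.77 between HDM and Grass, 0.56 between HDM and Cat and 0.68 between Grass and Cat (Spearman 0.8, 0.69 and 0.7). Simulated unchanged groups that share simulated untreated libraries gave r = 0.52, 0.51 and 0.52. The simulations do not hold the deviations of the real untreated libraries, so the real shared controls may add more. The covariances were 0.0395, 0.0218 and 0.0265, against 0.0065, 0.0065 and 0.0066 simulated. All 3 extracts raised 345 genes and lowered 1199 with the deposited scaling, 528 and 774 with DESeq2's factors, and 762 and 530 with upper-quartile factors, where the higher genes outnumber the lower ones. Independent lists would share 4.8 and 87.1. The simulated unchanged groups shared 0 and 0, but almost no gene is called in them, so this does not measure what shared controls add to groups that change. Without Cat 1 and Cat 2 the shared genes higher were 188 and 160 and those lower 757 and 628. Genes of both shared lists are described above, such as Slc7a11 and H1f0. The 2 untreated libraries could not be divided, so part of the excess may come from the shared controls.

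**Figure D3:**
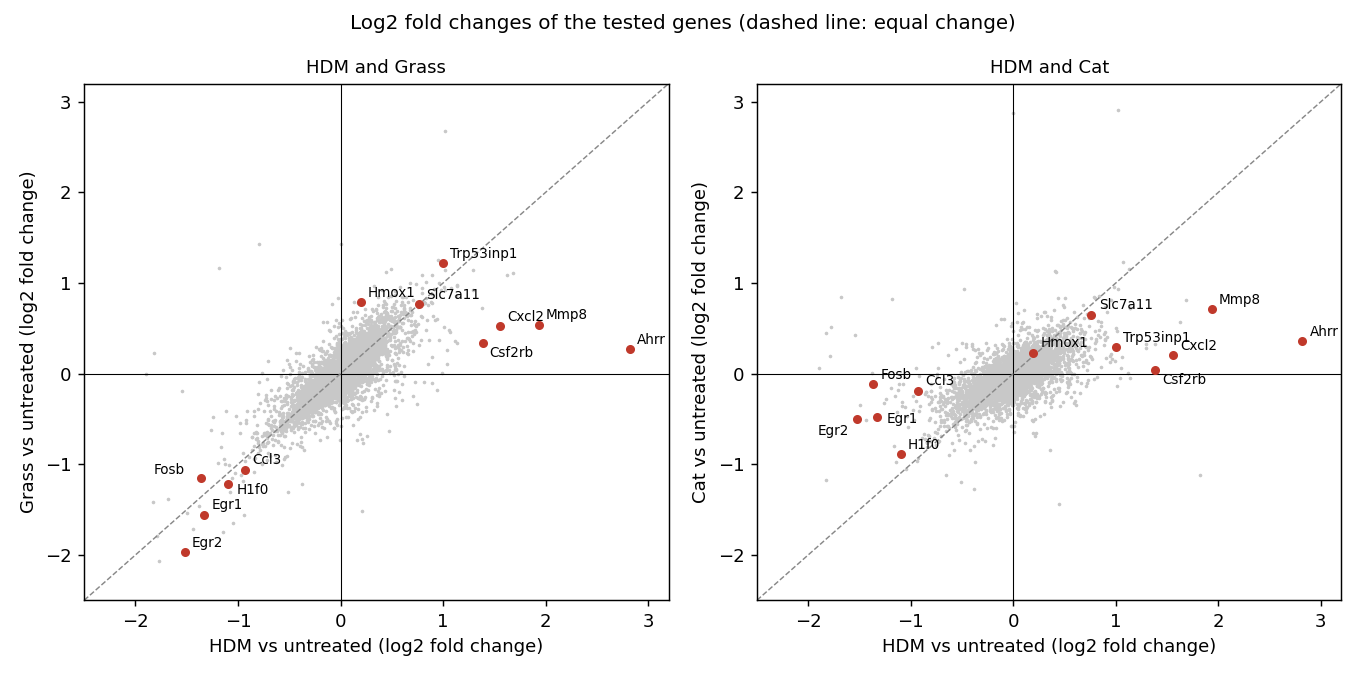
Log2 fold changes against untreated of 11455 genes, HDM on the x axis and Grass (left) or Cat (right) on the y axis, with 1 point per gene, 12 genes named and a dashed line of equal change. Ahrr lies at 2.82 with HDM and far below the line in both panels, and 4 genes in the left panel and 5 in the right lie outside the axes.

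Among the other lists, markers of dendritic cell identity fell more often than they rose: 8 of 15 lower and 1 higher with HDM, 6 and 1 with Grass, and 6 and 0 with Cat. Called genes as a whole did the same under the deposited scaling, with 29.6%, 29.1% and 24.1% of calls higher. Bst2 is a member of both this list and the interferon list. Cd24a fell by 0.45, 0.57 and 0.26 (SE 0.03 each) and Irf8, a factor of dendritic cell development, by 0.53 with HDM and with Grass (SE 0.04 each), while 5 markers fell with HDM when HDM 2 was left out. Macrophage and monocyte markers went both ways (of 13, 4 higher and 4 lower with HDM, 1 and 4 with Grass, 0 and 3 with Cat). Cholesterol synthesis genes rose in 8, 10 and 1 of 23 and fell in 5, 6 and 4, and those of the unfolded protein and integrated stress responses rose in 6, 5 and 4 of 24 and fell in 11, 10 and 6. In the latter, Trib3 rose by 0.49, 0.40 and 0.24 (SE 0.03 each) and the chaperone Hsp90b1 fell by 0.17, 0.19 and 0.14 (SE 0.03 each). Nucleic acid and microbial sensors rose in 6, 5 and 2 of 25 and fell in 6, 7 and 5, with Mavs, the adaptor of RNA sensing, higher by 0.19, 0.27 and 0.18 (SE 0.04 each). Type 2 polarising and allergen response factors rose in 3, 2 and 1 of 8 and fell in 2, 2 and 0. Il1rl1, the IL-33 receptor, fell by 0.25 with HDM and 0.32 with Grass (SE 0.05 each). Maturation genes rose in 2, 2 and 0 of 13 and fell in 1, 0 and 2. TGF-beta and matrix genes rose in 1, 1 and 0 of 10 and fell in 4, 3 and 1, and heat shock genes rose in 1, 3 and 1 of 12 and fell in 2, 2 and 0. MHC class II genes fell in 1, 2 and 2 of 6 and rose in 0, and interferons and their receptors rose in 1, 1 and 0 of 6 and fell in 1, 3 and 3. Adjusted over the list alone, these counts moved by at most 2. Markers of other cells were mostly below the filter: 0 of 15 granulocyte, mast cell and erythroid markers passed it, as did 2 of 16 lymphocyte markers and 1 of 16 fibroblast and epithelial markers, and 0 of these were called. Many of these counts moved by over 1.5 times without a single library. Cholesterol genes higher with HDM numbered 2 without HDM 1 and 4 without HDM 2 or untreated 2, and those higher with Grass 6 without Grass 2 or untreated 2. Sensors lower numbered 2 with HDM without HDM 2, 2 with Grass without Grass 2 and 0 with Cat without Cat 2, and stress response genes lower numbered 7 with HDM without HDM 2 and 2 with Cat without Cat 1. The scaling moved them too: with DESeq2's factors sensors lower numbered 2 with HDM and 3 with Grass, stress response genes lower 7 with HDM, 7 with Grass and 3 with Cat, maturation genes higher 4 with HDM, heat shock genes higher 3 with HDM and 3 with Cat, and cholesterol genes 3 higher and 2 lower with Cat. With these factors the other counts moved by at most 2 genes, and several moved further with upper-quartile factors. With the preset correlation, camera passed dendritic cell identity with Cat (adjusted p = 0.042, and adjusted p = 0.44 with an estimated correlation) and maturation genes with HDM (adjusted p = 0.05 after rounding up to the threshold, and adjusted p = 0.42 with an estimated correlation), and no other of these lists against untreated. The median fold change of the stress response, heat shock, sensing, TGF-beta, macrophage, maturation and interferon receptor lists changed sign with the scaling in at least 1 comparison with untreated. Median, mean and camera's direction differed in sign for cytokines with HDM (median -0.12, mean 0.08), for NF-kB genes with Grass (0.01 and -0.05) and Cat (0.02 and -0.01), and for stress response, heat shock, sensing, maturation, macrophage or cholesterol genes in at least 1 comparison each.

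The authors' own tables, from another test on the same values, list 115 genes higher and 97 lower with HDM, 132 and 91 with Grass, and 20 and 33 with Cat. Of these, 193, 203 and 35 in total were called in the same direction by limma and 0 in the opposite one. The authors' FDR was under 0.05 for 195, 194 and 31 of the listed genes. Their tables hold 13, 9 and 8 interferon-stimulated genes lower and 0 higher. The smallest deposited folds in them were 1.502, 1.501 and 1.507, and the largest deposited p-values 0.035, 0.048 and 0.018. Smaller changes are thus left out, and these counts are not comparable with limma's, which had no fold minimum. Amd1 is listed in all 3 but was not called by limma. It and its copy Amd2 summed to between 164 and 209 in every library while Amd1 alone ranged from 0.896 to 137, so both are uncertain.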

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

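The tests of an aryl hydrocarbon receptor ligand and of the stress response were chosen after the values were seen, and the list of receptor targets was written after 6 of its 8 members with a read had been looked at, among them Ahrr, Tiparp and Cyp1b1.

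The response to HDM differed from that to the other extracts at targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds. Besides Ahrr (2.82, SE 0.14), HDM raised Tiparp (0.38), which both other extracts lowered (-0.24 and -0.30), and Cyp1b1 had 9 and 10 reads in the HDM libraries and 0 or 1 in each other. If a shared oxidative stress response raised these targets, Grass would raise them no less, since its Nrf2 genes rose no less. Over the 5 tested targets the median difference between HDM and Grass was 0.75, with Nqo1 the smallest (0.17, limma adjusted p = 0.55). The test cannot decide, because most of these targets were listed with their values known and the median counts both Ugt1a6a and Ugt1a6b. A ligand in the mite extract is a candidate explanation that cannot be told apart from a chance choice of genes, because most of the list was picked with its values known. The members not looked at before, Ugt1a6a and Ugt1a6b, share exons and count as 1 locus, 0.85 higher with HDM than with Grass and 0.82 than with Cat, while Cyp1a1, a usual target, had 0 to 2 reads per library and no excess with HDM.

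The test between extracts called 265 genes for HDM against Grass, and 11 genes were called in opposite directions against untreated, such as Eepd1 (0.52 and -0.18), Tiparp (0.38 and -0.24) and Ggta1 (0.40 and -0.21). For HDM against Cat it called 889 genes, with 12 in opposite directions, such as the IL-7 receptor Il7r (0.26 and -0.47), Smox, a polyamine oxidase (0.55 and -0.11), and the co-stimulatory receptor Cd28 (0.44 and -0.19). For Grass against Cat it called 1353 genes, with 8 in opposite directions, such as Hbp1 (0.27 and -0.12) and the cholesterol transporter Abcg1 (0.18 and -0.17). The test of the difference passed for each gene named here, and all were chosen after their values were seen. These 3 totals moved by over 1.5 times with single libraries left out, as given with the comparisons between extracts.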

How the results depend on the processing

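The tests with edgeR on recovered reads, TMM factors, pseudocounts of 0.5 and 1 and a GC and length trend removed, the exact permutation of list scores, and the counts of list members under all settings, were chosen after seeing the data. The written design had named edgeR with TMM and filterByExpr, for counts. Except where the alternative itself explains it, the cause was not tested. Interferon list medians against untreated kept their direction under all settings tried, which left out the tests on recovered reads. Correlations of responses were recomputed only with the stricter filter and with each library left out, and stayed positive. Simulated unchanged groups with shared controls also gave positive correlations, so this sign does not speak for a shared response. Of 8711 values of named genes, 7864 stayed on the same side of the threshold, and among called genes 1 reversed (Hsp90ab1 with HDM, 0.01 with upper-quartile factors, adjusted p = 0.65 by limma). The other pseudocounts, stricter filter, GC and length trend, edgeR with the deposited scaling and limma-voom moved no count by over 1.5 times.

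Upper-quartile factors gave 2169 higher and 1156 lower with HDM, 2459 and 1338 with Grass, 1048 and 834 with Cat, and 762 and 530 with all 3. DESeq2's factors gave 762 higher with Cat and 528 higher and 774 lower with all 3. TMM gave 1930 lower with Grass, 764 higher with Cat, and 529 higher and 770 lower with all 3. By construction, a minimum of 1.5-fold left fewer genes: 105 and 113 with HDM, 117 and 111 with Grass, 19 and 26 with Cat, 10 and 11 with all 3, 23, 67 and 50 between extracts (HDM and Grass, HDM and Cat, Grass and Cat), and 11, 8 and 5 interferon list members lower with HDM, Grass and Cat. The exact test at an unadjusted p with 1.5-fold gave 129 and 154, 166 and 147, 44 and 63, and 13, 12 and 11 members. DESeq2 on recovered reads gave 548, 707 and 203 higher, 146 higher with all 3, and 165, 532 and 788 between extracts. EdgeR with TMM and filterByExpr gave 1465 higher and 1579 lower with HDM, 1684 and 1892 with Grass, and 719 and 998 with Cat. It gave 718 lower with all 3. Only the 4 libraries compared gave 297 higher with Cat, 210 higher with all 3 and 595 between HDM and Grass, and no filter 163 between HDM and Grass. An estimated correlation left the interferon medians at -0.42, -0.44 and -0.41 but gave camera adjusted p = 0.42, 0.59 and 0.44.

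With 1 library left out, counts ranged from 613 to 1017 higher and 1660 to 2620 lower with HDM, 775 to 1172 and 2104 to 3008 with Grass, 201 to 573 and 754 to 1942 with Cat, 160 to 396 and 628 to 1518 with all 3, 108 to 566, 438 to 1278 and 535 to 1955 between extracts, and 22 to 49, 27 to 51 and 14 to 52 interferon list members. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.08 to 0.13 between groups. With a replicate block the counts were 1031 and 2458 with HDM, 1182 and 2861 with Grass, 472 and 1485 with Cat, 334 and 1132 with all 3, 256, 850 and 1312 between extracts and 29, 35 and 29 interferon list members.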

Other observations

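The tests of untreated 2, of the scaling, of the untreated cultures and of DNA replication were chosen after the results were seen, as were the lists of mitotic, replication and histone genes and their subsets, while the test of RNAs without a poly-A tail was written before its result.

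Lists of mitotic and DNA replication genes were written after the divide within the cell cycle list was seen, and share members with it. Of 40 DNA replication genes, 20 rose with HDM, 27 with Grass and 19 with Cat, and 1 fell with Grass, with median log2 fold changes of 0.09, 0.14 and 0.09. These counts were 12 to 21, 18 to 30 and 13 to 22 with 1 library left out, 14, 21 and 15 with DESeq2 and 31, 39 and 26 with upper-quartile factors. Of 35 mitotic genes, 30 fell with each extract and 0 rose by limma, with medians of -0.27, -0.31 and -0.24. Summed over its members, the deposited values of the mitotic list went from 5920 in untreated cells to 4910, 4780 and 5030. Outside the cell cycle list, 15 of 17 mitotic genes fell with each extract (medians -0.27, -0.35 and -0.29), and 13, 20 and 11 of 28 replication genes rose (medians 0.10, 0.14 and 0.09), or 6 to 12, 11 to 19 and 7 to 13 with 1 library left out. In all 3 comparisons Ccne1 rose (0.32, 0.42 and 0.31, SE 0.04 each), as did Mcm7 of the replicative helicase (0.18, 0.24 and 0.16, SE 0.03 each). Cyclin D1 (Ccnd1) fell (-0.36, -0.38 and -0.14, SE 0.04 each). These 3 genes were chosen after their values were seen.

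Transcripts of replication-dependent histone genes, most of which lack a poly-A tail, fell in 20 of 41 with HDM, 17 with Grass and 12 with Cat (medians -0.59, -0.51 and -0.25). These counts were 13 to 20, 13 to 18 and 7 to 12 with 1 library left out, and 12, 11 and 4 with DESeq2. Reads may be split between near-identical copies in this family, so the counts of single members are uncertain. Summed over the 65 members with a read, the deposited values went from 541 in untreated cells to 407, 379 and 439. Fewer cells replicating DNA would lower replication genes as well, but the lowest of the 3 medians of those outside the cell cycle list was 0.09. Less carry-over of RNAs without a poly-A tail cannot be told apart from a biological change: the 3 other RNAs of this kind that were tested had a highest median of 0.25, and all 19 with a read, summed, changed by 0.18, -0.34 and 0.12 in log2, less than the spread between the HDM libraries (7.31 and 2.71, against 3.55 and 5.31 untreated). A change in histone transcript turnover was not tested.

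The lower interferon-stimulated genes were weighed against 3 explanations. Untreated 2 alone is argued against by medians of -0.27 or lower in all 3 comparisons without it, and the deposited scaling by medians of -0.34 or lower with the 3 other scalings. The untreated cultures may instead have been in a raised interferon state for a reason apart from the missing extract. Their own list scores differed by 0.26, where the allergen minus untreated difference was -0.44, and 2 untreated cultures cannot decide this. Such a state cannot be told apart from a lowering by the extracts, because the same 2 untreated cultures serve all 3 comparisons. The labels name no vehicle, and an exchange of whole group labels was not tested. A lowering by each extract stays open as the biological explanation. The limit of shared untreated cultures holds for the other lists as well.

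Transcripts of several mediators were near or below the floor in every library. Il6 had 0 to 2 reads per library, Il1b 0 to 5 and Ccl17 0 to 1. A fall or a small change in these genes was thus not detectable at this depth. A rise of any of them to the filter's value of 0.5 would have been seen. Their highest values in any library were 0.0615, 0.138 and 0.0226, in the order given. No pair of libraries looked like a copy, by the chi-square per gene between their read counts, where 1 is counting error alone. It was 4.69 for the untreated pair, 2.31 for HDM, 2.98 for Grass and 2.21 for Cat, and 5.6 to 28.67 between groups. The untreated libraries thus differed most within a group. The main fit held 1 variance per gene for all groups. Its p-values against untreated rest on a spread averaged with the closer pairs. Those between extracts rest on a spread that includes the untreated pair. A variance per group was not fitted.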
